A study of Rattus norvegicus with 18 samples.

How the data were processed

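Total RNA of rat lung was labelled with biotin as cRNA and hybridised to 2 Affymetrix array types, per the labels. The 18 samples are 9 conditions (3 exposures and 3 recovery times) on each type, with 1 array per condition and type. The number of animals per array is not stated. The deposited values are signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, which give no version, masks or detection calls. In the deposited values the mean without the highest and lowest 2% was 500.09 to 500.10 on every array, so the authors' intensity scaling was kept. Median signals were 263.6 to 278.5 on type A and 315.3 to 338.7 on type B. The 3'/5' signal ratios of the control probe sets were 1.09 to 1.25 (A) and 0.976 to 1.16 (B) for GAPDH, 1.25 to 1.43 and 1.34 to 1.58 for actin, and 2.62 to 4.52 and 2.56 to 4.72 for hexokinase.

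Samples were grouped by title. For the 4 smoke samples at 20 h a further label says sham, while title and source name the smoke exposure, and results without the 20 h conditions were computed as an alternative. No genome was given, and gene symbols came from an annotation table updated through Entrez identifiers. Of 15923 probe sets on type A, 12789 had 1 symbol, 312 several and 2822 were not listed. Of 15333 on type B, 7570 had 1 symbol, 100 several and 7663 were not listed.

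Signals were analysed as log2(signal + 50), where 50 is 0.1 of the trimmed mean. All log2 changes and folds are on that scale, so folds of dim probe sets are smaller than the ratios of their signals. Probe sets were kept at or above the 40th percentile of their type (183.8 on A, 238.7 on B) in at least 3 of 9 arrays. The 57 control probe sets of each type were left out, and 100 probe sets on both types were tested on A only. This left 9901 probe sets on A and 9737 on B, 19638 in all, of which 13811 had 1 symbol, for 10165 genes.

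Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), separately for each array type, with Benjamini-Hochberg adjustment over both types together and a threshold of 0.05. Tests were two-sided. The first model held exposure and recovery time without interaction (4 residual degrees of freedom) and gave the comparisons of 600 and 300 µg/l with sham, of 600 with 300 µg/l, of any difference among exposures (moderated F), and of 6 and 20 h with 2 h. The second held smoke (both levels together against sham), time and their interaction (3 residual degrees of freedom) and gave the difference of the smoke effect at 6 or 20 h from that at 2 h. Its residual spread is that between 300 and 600 µg/l within a time, so its SEs and calls, over the list alone as well, hold no measured variation of sham arrays. A model with all 9 conditions has no residual degrees of freedom. Since no condition had a replicate, p-values measure only the spread between these arrays.

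The 32 gene lists were fixed before the data were examined, as were the comparisons, the main alternative settings and the rule for named genes. For each gene the probe set with the highest mean signal was used. The 27 lists with at least 4 measured genes were tested in 5 comparisons (135 tests) with limma's camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Changes of single members were also adjusted over the list alone. No list test was run on the differences of smoke effects. The lists cover AhR-induced xenobiotic metabolism, NRF2 antioxidant and NADPH genes, chemokines and cytokines, acute inflammatory effectors, macrophage and lysosome, neutrophil, core clock and clock output, immediate early, glucocorticoid-responsive, alveolar type 2 and surfactant, alveolar type 1, club and secretory airway, ciliated cell, endothelial, T cell, B cell and plasma cell, NK and cytotoxic, mast cell, extracellular matrix and fibroblast, smooth muscle, heat shock and unfolded protein, cell cycle, p53 and DNA damage, interferon-responsive, MHC class II, sterol and fatty acid synthesis, erythroid, cardiac muscle, skeletal muscle, adipose, thymus and lymph node, and cartilage genes.

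The text names, for 600 and 300 µg/l against sham, up to 10 genes that rose and 10 that fell most among those past the threshold with 1 symbol, the same sign at all 3 times and the highest mean signal of their gene. For the other comparisons it names up to 5 per direction, or, with no call, the 5 with the smallest p. It further names up to 4 members of each list by adjusted p, and always Cyp1a1, Cyp1b1, Nqo1, Hmox1, Gclc, Bmal1, Npas2, Nr1d1, Per2 and Dbp. Unnamed loci were counted only. Which list members were printed was chosen after their values were seen, and genes outside the rule are marked in the text as chosen later.

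The alternative settings chosen then were quantile normalization, median scaling, 0.25 (12.5) or 4 times (200) the pseudocount, no filter or the 60th percentile, no intensity trend, adjustment within each type, only the 2 exposures compared, no other factor, a linear slope over dose, no 20 h conditions, and leaving out each condition in turn. Type A alone, and leaving out the B array labelled sham at 2 h alone or with that labelled 300 µg/l at 2 h, were chosen after seeing the data. Values per recovery time come from the second model and were chosen after the main results were seen.

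The method was tested on simulated data in 10 runs with 200 of 19638 probe sets changed. With variances drawn from limma's prior, 18.6% of changes of 0.5 and 79.2% of changes of 1 (log2) were called for 600 µg/l against sham, and 3.55% of calls were false. For the difference of the smoke effect at 20 and 2 h, 9.2% of changes of 1 and 74.2% of changes of 2 were called, and 5.55% of calls were false. With each gene's own moderated variance, which had been run first, the shares called were 37.7% and 91.0%, with 8.72% of calls false, and 30.6% and 90.0%, with 9.26% false. The prior-based simulation was added after the result of the first was seen. Both drew independent normal noise, with the same variance for sham and smoke arrays of a probe set, and held no doubtful array. Their shares of false calls hold only where these assumptions do. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.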

Results

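Lung RNA of male Sprague-Dawley rats was measured on a pair of Affymetrix array types, called A and B here, which carry mostly different probe sets. The rats had inhaled mainstream smoke of a reference cigarette through the nose, or had been sham-exposed, for 2 h a day on 5 days a week over 13 weeks. Smoke was given at 300 or 600 µg of total particulate matter (TPM) per litre, and lungs were taken 2, 6 or 20 h after the last session. The 3 exposures and 3 recovery times made 9 conditions, each with 1 array of each type, 18 arrays in all. The labels do not say how many animals each array holds. No condition had a replicate array, so each exposure was compared over its 3 recovery times (n = 3 arrays per exposure) and each recovery time over its 3 exposures. The spread behind each SE therefore holds array noise and any difference of the dose effect between times together, and the number of arrays limits the precision. In all, 19638 probe sets were tested.

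The type B array labelled sham at 2 h stood apart. Across probe sets, which are not independent replicates, its deviations from the mean array correlated with those of the B array labelled 300 µg/l at 2 h (r = 0.56), against at most 0.12 in the other 35 pairs of B arrays. The type A arrays with the same labels gave r = -0.16. Of the B probe sets of Plet1, a gene chosen after its values were seen, the brighter read 4351 on the array labelled sham at 2 h, 1840 and 1536 in sham at 6 and 20 h, and 4421 at 300 µg/l at 2 h. Its A probe set read 1081, 740 and 1034 in the same sham conditions and 2077 at 300 µg/l at 2 h. Counts of calls, and calls of named genes, without this array are given where it changed them. The types were fitted separately, so calls on type A then change only through the joint adjustment.

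The comparison of 600 µg/l with sham asks which genes of the lung differ after repeated exposure to the higher smoke concentration. Some inflammatory and macrophage genes rose. The neutrophil calcium-binding protein gene S100a9 rose 5.05-fold (log2 2.33, SE 0.22), the acidic chitinase gene Chia 4.63-fold (log2 2.21, SE 0.09), the metallothionein gene Mt2A 4.04-fold (log2 2.01, SE 0.21) and Lcn2, a siderophore-binding protein of innate defence, 3.81-fold (log2 1.93, SE 0.14). Among the genes that fell, Spon2, which encodes an extracellular matrix protein, fell by 1.32 on the log2 scale (SE 0.15) and the lung cytochrome P450 gene Cyp4b1 fell by 0.65 (SE 0.07). In all, 101 probe sets passed an adjusted p of 0.05, 84 higher and 17 lower, 92 of them on type A, and 31 changed at least 2-fold. Each of the 101 had the same sign at all 3 recovery times, which a call on the mean of these same differences makes likely in any case.

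**Figure D1:**
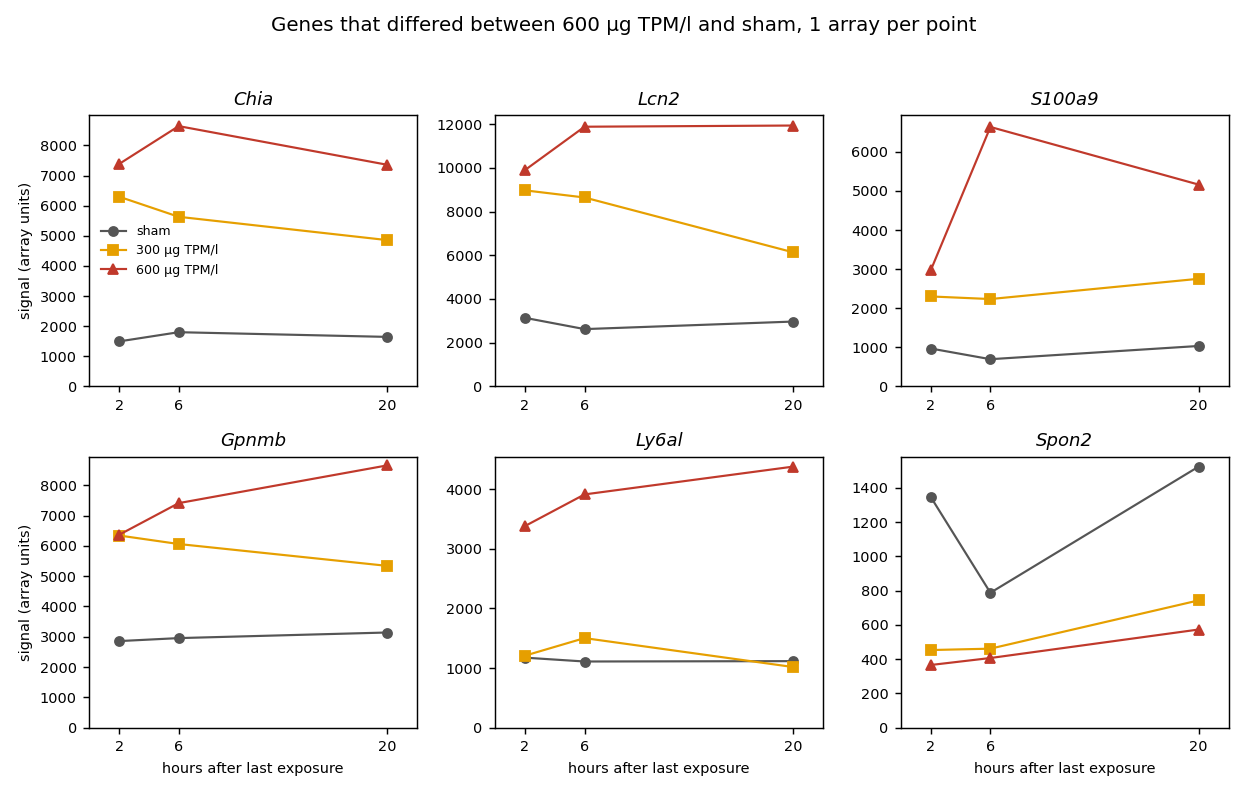
Signals (array units, linear axis) of 6 genes against hours after the last exposure, 1 array per point, in sham, 300 and 600 µg TPM/l. Chia, Lcn2, S100a9 and Gpnmb lie above sham at every time in both smoke groups, Ly6al lies above it at every time at 600 µg/l, and Spon2 lies below it in both groups.

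Of 19 measured macrophage and lysosome genes, 8 rose, none fell and 11 did not pass. Gpnmb rose 2.46-fold (log2 1.30, SE 0.11) and the endosomal marker gene Cd68 2.26-fold (log2 1.17, SE 0.09). The collagen-degrading protease gene Ctsk rose (log2 1.73, SE 0.19, 1.05 to 2.11 over the alternatives), its signals being 46.7 to 110.1 in sham, under the 183.8 of the filter on type A, and 327.7 to 432.6 at 600 µg/l, so the size of its rise is uncertain. The macrophage elastase gene Mmp12 also rose from dim signals in sham, 157.9 to 191.2 (log2 1.51, SE 0.27, 1.08 to 1.93 over the alternatives). When adjusted over the list alone, 15 passed, all higher. The list's median change was 0.63, and its camera test gave an adjusted p = 3.3e-20, but adjusted p = 0.32 with an estimated correlation. Leaving out the doubtful B array, 10 of the 19 rose.

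Of 17 chemokine and cytokine genes, 5 rose, 1 fell and 11 did not pass. The neutrophil-attracting chemokine gene Cxcl1 rose 2.52-fold (log2 1.33, SE 0.22). Cxcl2, another of them, rose by log2 1.17 (SE 0.18, 0.65 to 1.48 over the alternatives) from dim signals in sham (63.2 to 83.5), and Ccl3 and Ccl6 rose by log2 0.67 (SE 0.11) and 0.56 (SE 0.09). The remaining pair, outside the rule for named genes, was Il18, which rose by 0.50 (SE 0.09), and Ccl5, a T cell attractant, which fell by 0.55 (SE 0.10). Each of these 6 calls was lost under some alternatives, those of Ccl3 and Ccl5 under 13 of 24, Il18 under 12 of 24, Ccl6 under 9 of 24, Cxcl1 under 8 of 24 and Cxcl2 under 7 of 23. There were 10 higher and 1 lower when adjusted over the list alone. The median was 0.50 (camera adjusted p = 5.7e-09, and adjusted p = 0.36 with an estimated correlation). Of 11 acute inflammatory effectors, Lcn2 and the complement gene C3 (log2 1.20, SE 0.07) rose and 9 did not pass. Nos2, the inducible nitric oxide synthase gene, had a log2 change of -1.47 (SE 0.27, adjusted p = 0.051) on low signals. It is measured on type A, and passed without the doubtful B array through the joint adjustment alone (adjusted p = 0.048, range over all alternatives 0.011 to 0.22). Adjusted over the list alone, 4 were higher and 1 lower. The median was 0.15 (adjusted p = 0.010, and adjusted p = 0.36 with an estimated correlation). Of 4 neutrophil genes, S100a9 rose and 3 did not pass. Its partner S100a8 had a log2 change of 0.77 (SE 0.30, adjusted p = 0.40). There were 3 higher when adjusted over the list alone, and the median was 0.60 (adjusted p = 3.0e-04, and adjusted p = 0.37 with an estimated correlation).

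Of 28 genes of the NRF2 antioxidant response and NADPH supply, 2 rose and 26 did not pass. The heme oxygenase gene Hmox1 rose 1.94-fold (log2 0.96, SE 0.16) and the glutathione transferase gene Gstp1 1.46-fold (log2 0.55, SE 0.10). Gsta3 (log2 0.90, adjusted p = 0.075), Mgst2 (0.43, adjusted p = 0.059) and Gclc, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (0.43, adjusted p = 0.31), did not pass. When adjusted over the list alone, 14 were higher. The median was 0.32 (adjusted p = 2.8e-13, and adjusted p = 0.36 with an estimated correlation). None of 7 AhR-induced genes of xenobiotic metabolism passed over all genes tested by limma, where 2031 probe sets had an unadjusted p under 0.05. Adjusted over the list alone, 5 were higher. Cyp1a1, the classic target of the aryl hydrocarbon receptor, had a mean log2 change of 3.35 (SE 0.72, adjusted p = 0.097), Nqo1 of 1.25 (SE 0.30, adjusted p = 0.14), Cyp1b1 of 1.17 (SE 0.32, adjusted p = 0.20) and Tiparp of 0.49 (SE 0.12, adjusted p = 0.14). That Tiparp probe set, which is among the 5, is on type B with the doubtful array. Another Tiparp probe set, on type A, stood at -0.02 (SE 0.10, adjusted p = 0.96). Over the alternatives Cyp1a1 ran from 2.31 to 4.67 (adjusted p = 6.1e-04 to 0.43) and Nqo1 from 0.80 to 1.78 (adjusted p = 0.0030 to 0.41), and both passed under 2 of 24, without sham at 20 h and without the 20 h conditions. Cyp1b1 ran from 0.60 to 1.61 and passed under none. The list's median was 1.17 (adjusted p = 1.8e-04, and adjusted p = 0.36 with an estimated correlation). How these changes differed between recovery times is given with the differences between times.

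Of the glucocorticoid-responsive genes, 9 in number, Mt2A rose and 8 did not pass, with Fkbp5 at 0.67 (SE 0.23, adjusted p = 0.33). When adjusted over the list alone, 1 passed. The median was 0.16 (adjusted p = 0.013, and adjusted p = 0.42 with an estimated correlation). Of 8 MHC class II genes none passed. RT1-Da, on type A, stood at 0.33 (SE 0.06, adjusted p = 0.053) and passed without the doubtful B array, again through the joint adjustment alone (adjusted p = 0.0496, range over all alternatives 0.029 to 0.37), and RT1-DMa stood at 0.39 (SE 0.11, adjusted p = 0.20). Both were higher when adjusted over the list alone, and the median was 0.23 (adjusted p = 0.0029, and adjusted p = 0.37 with an estimated correlation). Of 17 sterol and fatty acid synthesis genes none passed, with Scd at 0.67 (SE 0.21) and Fdps at 0.42 (SE 0.14). Adjusted over the list alone, 4 were higher, and the median was 0.22 (adjusted p = 2.2e-04, and adjusted p = 0.46 with an estimated correlation).

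The 6 lists of this paragraph shifted downward in the camera test at the preset correlation, with few single genes past the threshold. None passed with an estimated correlation, and only the T cell list also passed with fry (adjusted p = 0.048). Of 17 extracellular matrix and fibroblast genes, Tnc, which encodes the matrix protein tenascin C, fell by 0.94 (SE 0.17) and 16 did not pass, with Col1a1 at -0.34 and Col3a1 at -0.24. There were 7 lower and 1 higher when adjusted over the list alone. The median was -0.19 (adjusted p = 0.0014, and adjusted p = 0.36 with an estimated correlation). None of 10 T cell genes passed over all genes. Adjusted over the list alone, 5 were lower, among them Cd3d at -0.45 (SE 0.16) and Cd3g at -0.40 (SE 0.10). The median was -0.35 (adjusted p = 1.0e-04, and adjusted p = 0.32 with an estimated correlation). None of 9 NK and cytotoxic genes passed, and adjusted over the list alone 2 were lower, Nkg7 at -0.51 and the perforin gene Prf1 at -0.46. The median was -0.32 (adjusted p = 0.0018, and adjusted p = 0.37 with an estimated correlation). None of 8 alveolar type 1 genes passed, and adjusted over the list alone 3 were lower, among them the water channel gene Aqp5 at -0.40 (SE 0.09) and Akap5 at -0.51 (SE 0.11). The median was -0.13 (adjusted p = 0.0021, and adjusted p = 0.36 with an estimated correlation). None of 11 endothelial genes passed, and adjusted over the list alone 2 were lower, Emcn at -0.38 and the receptor gene Tie1 at -0.31. The median was -0.15 (adjusted p = 0.0013, and adjusted p = 0.37 with an estimated correlation). None of 17 interferon-responsive genes passed under either adjustment, with Rsad2 at -0.31 and Gbp2 at -0.27. The median was -0.17 (adjusted p = 0.0021, and adjusted p = 0.46 with an estimated correlation).

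**Figure D2:**
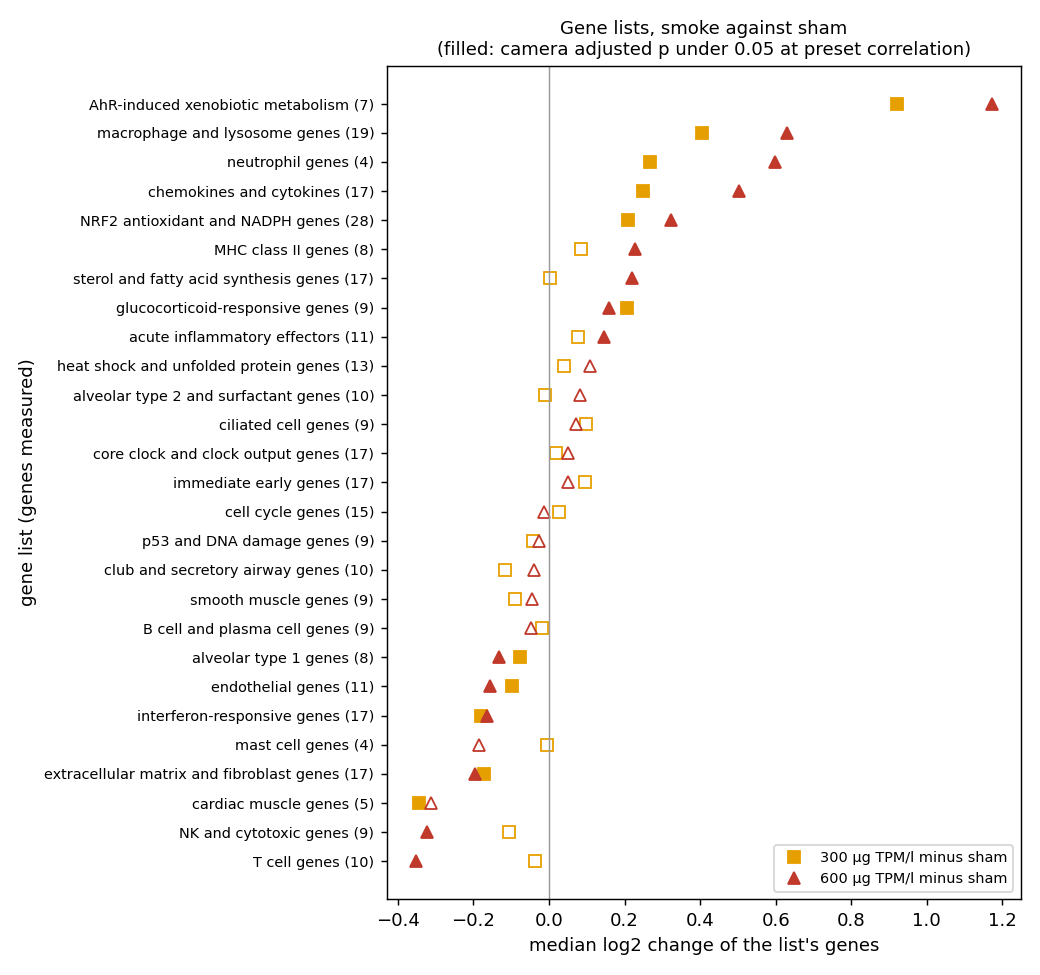
Median log2 change of the genes of each list (x axis) by list, with the number of genes measured, at 300 and 600 µg TPM/l against sham, filled where camera's adjusted p at the preset correlation was under 0.05. The AhR list has the largest median at 600 µg/l (1.17) and the macrophage list follows (0.63).

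The other 12 tested lists did not pass the camera test in this comparison. Core clock and clock output genes had a median of 0.05 over 17 genes (adjusted p = 0.56), with 1 riser, Bhlhe41, a transcriptional repressor of the clock loop (log2 1.05, SE 0.13). Immediate early genes had a median of 0.05 (adjusted p = 0.46), with Myc at 0.68 and Nr4a1 at -0.47. Alveolar type 2 and surfactant genes had a median of 0.08 (adjusted p = 0.18), with Sftpd at 0.19. Club and secretory airway genes had a median of -0.04 (adjusted p = 0.26). Cyp4b1 belongs to this list, and Cyp2f4 stood at -0.79 (adjusted p = 0.25). Ciliated cell genes had a median of 0.07 (adjusted p = 0.98), with Tppp3 at -0.32. B cell and plasma cell genes had a median of -0.05 (adjusted p = 0.98), with Xbp1 at 0.14. Mast cell genes had a median of -0.18 (adjusted p = 0.096), with Cpa3 at -0.31. Smooth muscle genes had a median of -0.05 (adjusted p = 0.46), with Smtn at -0.52. Heat shock and unfolded protein genes had a median of 0.11 (adjusted p = 0.27), with Hspd1 at 0.13. Cell cycle genes had a median of -0.01, a mean of 0.04 and a test in the upward direction (adjusted p = 0.65), with Stmn1 at -0.39. The p53 and DNA damage genes had a median of -0.03 (adjusted p = 0.21), with Sesn2 at -0.33. Cardiac muscle genes had a median of -0.31 (adjusted p = 0.095), with Actc1 at -0.44. The remaining 5 lists had too few genes for a test. Of 3 erythroid genes, Alas2, the first enzyme of heme synthesis in red cells, stood at -0.68 (adjusted p = 0.055) and the globin gene Hbb at -0.20. Medians were -0.06 for skeletal muscle, 0.02 for adipose tissue, -0.02 for thymus and lymph node, and -0.20 for cartilage.

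The further genes named by rule in this comparison were Ly6al, a Ly6 family member (log2 1.73, SE 0.14), and the anion exchanger gene Slc26a4 (log2 1.49, SE 0.27), which rose, and the lysosomal protease gene Ctsd, which rose by 0.92 (SE 0.06). Gja4, a gap junction gene of arterial endothelium, fell by 0.78 (SE 0.11), Tcim by 0.77 (SE 0.13), Lrrn3 by 0.68 (SE 0.10), the Wnt inhibitor gene Wif1 by 0.67 (SE 0.10), the sodium channel gene Scn7a by 0.66 (SE 0.10), Septin4 by 0.58 (SE 0.09) and the collagen gene Col5a2 by 0.57 (SE 0.10). The moderated F test of any difference among the 3 exposures passed for 42 probe sets (50 without the doubtful B array), and 1522 had an unadjusted p under 0.05. The count of 101 fell to 43 when the 600 µg/l arrays at 20 h were left out and to 35 with no filter on dim probe sets, and was 124 without the doubtful B array. S100a9, Chia, Mt2A, Lcn2, Ctsk, Ly6al, Gpnmb, C3, Cd68, Bhlhe41, Ctsd, Spon2 and Cyp4b1 kept their calls under every alternative that tested them. Besides the chemokine genes, calls were lost under 12 of 23 for Slc26a4 and Tnc, 11 of 24 for Hmox1, Gstp1 and Col5a2, 10 of 24 for Mmp12, Tcim and Septin4, 9 of 23 for Lrrn3, 8 of 24 for Wif1 and Scn7a and 7 of 24 for Gja4. Of the named genes not past, Nos2 gained a call under 12 of 23, RT1-Da under 6 of 24, Alas2 under 5 of 24, Mgst2 under 4 of 24, Gsta3 under 4 of 23, Cyp2f4 under 2 of 24, and Myc (of 23), Per2 and Tppp3 (of 24) under 1.

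At 300 µg/l the same question was asked of the lower concentration. Chia rose 3.32-fold (log2 1.73, SE 0.09), Lcn2 2.66-fold (log2 1.41, SE 0.14), Gpnmb 1.96-fold (log2 0.97, SE 0.11) and Cd68 1.80-fold (log2 0.85, SE 0.09) against sham. C3 rose by 0.73 (SE 0.07), Ctsd by 0.68 (SE 0.06) and Naaa, which encodes a lysosomal amidase, by 0.60 (SE 0.07). In all 9 probe sets passed, 8 higher and 1 lower, all on type A, and 1085 had an unadjusted p under 0.05. The other 2 were named after their values were seen. The A probe set of Plet1 rose by 0.93 (SE 0.11, adjusted p = 0.022). Its brighter probe sets, on type B with the doubtful array, stood at 0.66 (adjusted p = 0.71) and 0.70 (adjusted p = 0.82). A probe set of the small GTPase gene Rab15 fell by 1.50 (SE 0.15, adjusted p = 0.0066, -1.94 to -0.82 over the alternatives). Its signals at 300 µg/l, 53.9 to 56.4, lay under the filter of its type, so the size of its fall is uncertain. The brighter Rab15 probe set, on type B, stood at -0.18 (SE 0.10, adjusted p = 0.96). Of the 9 calls only that of Chia held under every alternative. Lcn2, Gpnmb, Cd68 and C3 lost theirs under 6 of 23, Ctsd under 5 of 23, Naaa under 12 of 23, the Plet1 probe set under 8 of 23 and the Rab15 probe set under 4 of 22. S100a9 stood at 1.40 (SE 0.22, adjusted p = 0.077), passing under 5 of 23, and Hmox1 at 0.53 (SE 0.16, adjusted p = 0.69).

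By list at 300 µg/l, 3 of 19 macrophage and lysosome genes rose (Gpnmb, Cd68 and Ctsd) and 16 did not pass, with Lgals3 at 0.56 (adjusted p = 0.062). In total 10 were higher when adjusted over the list alone, and the median was 0.41 (adjusted p = 1.3e-15, and adjusted p = 0.33 with an estimated correlation). None of 7 AhR genes passed, with Cyp1a1 at 3.45 (SE 0.72, adjusted p = 0.25), Aldh3a1 at 1.61 (SE 0.59), Nqo1 at 1.07 (SE 0.30) and Cyp1b1 at 0.92 (SE 0.32). Cyp1a1 ran from 2.41 to 4.79 over the alternatives (adjusted p = 5.1e-04 to 0.92) and Nqo1 from 0.62 to 1.60 (lowest adjusted p = 0.018), each passing under 2 of 23, again those without sham at 20 h and without the 20 h conditions. Aldh3a1 ran from 0.56 to 2.43 and Cyp1b1 from 0.35 to 1.28, neither passing under any alternative. Adjusted over the list alone, 4 were higher, and the median was 0.92 (adjusted p = 1.3e-04, and adjusted p = 0.36 with an estimated correlation). None of 28 NRF2 genes passed, with Gstm1 at 0.51, Gstp1 at 0.41 and Gclc at 0.15. Of them 7 were higher when adjusted over the list alone, and the median was 0.21 (adjusted p = 5.0e-09, and adjusted p = 0.37 with an estimated correlation). None of 17 chemokine and cytokine genes passed, with Cxcl2 at 0.74 and the interleukin gene Il1b at 0.63. Of these, 6 were higher when adjusted over the list alone, and the median was 0.25 (adjusted p = 1.4e-04, and adjusted p = 0.37 with an estimated correlation). None of 17 matrix genes passed, with Tnc at -0.73 and Col1a1 at -0.38. Of these genes 4 were lower when adjusted over the list alone, and the median was -0.17 (adjusted p = 5.6e-05, and adjusted p = 0.32 with an estimated correlation). Neutrophil genes (median 0.27, adjusted p = 0.0024) and glucocorticoid-responsive genes (0.21, adjusted p = 0.0013) passed upward, and interferon-responsive (-0.18, adjusted p = 2.2e-04), alveolar type 1 (-0.08, adjusted p = 0.0021), endothelial (-0.10, adjusted p = 0.0087) and cardiac muscle genes (-0.34, adjusted p = 0.024) downward (adjusted p = 0.36 to 0.48 with an estimated correlation). In all, 11 of 27 lists passed at the preset correlation, 6 upward and 5 downward, and 0 passed camera with an estimated correlation. The always-named clock genes stood at 0.69 (Per2), 0.50 (Dbp), -0.33 (Npas2), -0.04 (Bmal1) and -0.03 (Nr1d1), none past the threshold. The 9 calls became 1 with no filter, 2 when either the sham or the 300 µg/l arrays at 2 h were left out, 29 on type A alone and 10 without the doubtful B array.

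The comparison of both smoke levels asks where the higher concentration differs from the lower. Ly6al was 3.07-fold higher at 600 than at 300 µg/l (log2 1.62, SE 0.14, adjusted p = 0.0048), a call lost under 4 of 22 alternatives. Arg1, the arginase gene that marks alternatively activated macrophages, was 1.72-fold higher (log2 0.78, SE 0.09, adjusted p = 0.036), a call lost under 15 of 23 alternatives (adjusted p up to 0.53), with mean signals of 282 in sham, 422 at 300 µg/l and 762 at 600 µg/l. The other 2 of the 4 probe sets past the threshold were named after their values were seen. The A probe set of Rab15 was higher by 2.03 (SE 0.15, 1.18 to 2.54 over the alternatives). Its signals were between 54 and 57 at 300 µg/l, 182 to 311 in sham and 349 to 419 at 600 µg/l. Those at 300 µg/l lay under the filter, so the size of its difference is uncertain. A type A probe set without a gene symbol was higher by 1.20 (SE 0.12, adjusted p = 0.0099). Its signals at 300 µg/l, 105.3 to 174.1, also lay under the filter. It ranged from 0.77 to 1.41 over the alternatives and lost its call under 8 of 22. At an unadjusted p under 0.05 there were 992.

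Between the smoke levels the macrophage list had a median of 0.24 (adjusted p = 5.1e-10, and adjusted p = 0.36 with an estimated correlation), with 0 of 19 genes past the threshold over all genes and 9 higher when adjusted over the list alone. The sterol and fatty acid list had a median of 0.19 (adjusted p = 1.3e-06, and adjusted p = 0.37 with an estimated correlation) and the T cell list of -0.25 (adjusted p = 2.2e-05, and adjusted p = 0.32 with an estimated correlation), with 0 and 2 genes past when adjusted over the list alone. NRF2 (0.14), chemokine and cytokine (0.14), acute inflammatory (0.14) and neutrophil genes (0.35) also passed upward, and NK and cytotoxic (-0.20) and mast cell genes (-0.19) downward, at the preset correlation (adjusted p = 2.2e-04, 2.2e-04, 0.015, 0.024, 0.026 and 0.048). In all 9 of 27 lists passed at the preset correlation, and camera with an estimated correlation passed 0. The AhR list did not pass (median -0.01, mean 0.08, test in the upward direction, adjusted p = 0.44). The 4 calls became 1 with the 60th percentile filter, or when the 300 µg/l arrays at 2 h or the 600 µg/l arrays at 6 h were left out.

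Recovery times were compared over all exposures to ask which genes differ with the hours since the last session. The labels do not give the hour of day at which lungs were taken. Maob, which encodes the amine-degrading enzyme monoamine oxidase B, was 1.75-fold higher at 6 than at 2 h (log2 0.81, SE 0.10) and 1.74-fold higher at 20 than at 2 h (log2 0.80, SE 0.10). Cyp26b1, which degrades retinoic acid, rose 3.51-fold from 2 to 20 h (log2 1.81, SE 0.19) and the RING finger gene rnf141 1.78-fold (log2 0.83, SE 0.10). Ms4a7, a membrane protein gene, fell by 2.73 (SE 0.35). In all 3 probe sets passed at 6 h (1 higher, 2 lower, the latter unnamed) and 10 at 20 h (6 higher, 4 lower, 6 without a single gene symbol), against 2118 and 2247 at an unadjusted p under 0.05. At 20 h, 9 of the 10 were on type B. Leaving out the doubtful B array gave 1 and 0 calls, and type A alone gave 0 and 0. The Maob call at 6 h was lost under 14 of 21 alternatives, and at 20 h Maob, Cyp26b1, rnf141 and Ms4a7 lost theirs under 10 of 21, 9 of 20, 10 of 20 and 11 of 20.

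Of 7 AhR genes, none passed between 2 and 20 h over all genes. When adjusted over the list alone, 5 were lower and 1 higher, with Cyp1a1 at -3.58 (SE 0.72) and Ahrr, the receptor's repressor, at -1.56 (SE 0.23, adjusted p = 0.056). Ahrr was measured on type B, where the doubtful array is 1 of the 3 at 2 h, and it ranged from -1.86 to -0.96 over the alternatives (adjusted p = 0.023 to 0.75), the smallest change being that without the B arrays labelled sham and 300 µg/l at 2 h. The median was -1.35 (adjusted p = 0.0021, and adjusted p = 0.37 with an estimated correlation). Of 28 NRF2 genes none passed, and adjusted over the list alone 6 were lower, among them Nqo1 at -1.13, Akr1b8 at -0.80 and Hmox1 at -0.76. The median was -0.18 (adjusted p = 2.2e-05, and adjusted p = 0.42 with an estimated correlation). Of 13 heat shock and unfolded protein genes none passed, and adjusted over the list alone 3 were lower, among them the chaperone gene Hspa1a at -0.97 (SE 0.15, adjusted p = 0.064) and Ddit3 at -0.51 (SE 0.09, adjusted p = 0.096). The median was -0.15 (adjusted p = 0.0010, and adjusted p = 0.37 with an estimated correlation). Of 17 sterol and fatty acid genes none passed, and adjusted over the list alone 2 were higher, the desaturase gene Scd at 1.41 (SE 0.21, adjusted p = 0.056) and its paralog Scd2 at 0.42. The median was 0.11 (adjusted p = 0.0087, and adjusted p = 0.57 with an estimated correlation). T cell (median 0.14, adjusted p = 0.0079), alveolar type 2 (0.09, adjusted p = 0.013) and alveolar type 1 genes (0.13, adjusted p = 0.023) passed upward, and cardiac muscle genes (-0.32, adjusted p = 0.031) downward (adjusted p = 0.36 to 0.48 with an estimated correlation). These shifts of cell type markers between the times hold at the preset correlation only. In total 8 of 27 lists passed at 20 h and 4 at 6 h at the preset correlation, and 0 with an estimated correlation in camera. The lists past at 6 h were sterol and fatty acid synthesis (median 0.16, adjusted p = 2.7e-04, and adjusted p = 0.47 with an estimated correlation) and alveolar type 2 genes (0.13, adjusted p = 0.0042, and adjusted p = 0.37 with an estimated correlation). Immediate early genes (-0.17, adjusted p = 0.014, and adjusted p = 0.46 with an estimated correlation) and glucocorticoid-responsive genes (-0.19, adjusted p = 0.029, and adjusted p = 0.46 with an estimated correlation) passed downward.

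The difference of the smoke effect between recovery times asks which changes fade or build up after the last session, with both smoke levels pooled against sham. The spread in this model comes from the 300 and 600 µg/l arrays alone, and the 1 sham array of each type at each time is assumed to vary like them. The smoke effect on Cyp1a1 fell by 4.72 on the log2 scale from 2 to 20 h (SE 0.23, adjusted p = 2.3e-04), and that on Aldh3a1, an aldehyde dehydrogenase gene induced through the same receptor, fell by 3.74 (SE 0.37, adjusted p = 0.041). Cyp1a1 signals were 8795 and 9463 at 300 and 600 µg/l at 2 h, 2789 and 2122 at 6 h, and 209 and 207 at 20 h, against 102 to 154 in sham. All of these sham signals lay under the 183.8 of the filter, so the size of the excess over sham is uncertain. These 2 were the only probe sets past the threshold, and 678 had an unadjusted p under 0.05. Nqo1 (-1.95, SE 0.21, adjusted p = 0.054) and Cyp1b1 (-1.87, SE 0.29, adjusted p = 0.43) did not pass over all genes. When adjusted over the list alone, 4 AhR genes had a lower effect at 20 h than at 2 h, and 3 NRF2 genes did, Nqo1, Osgin1 (-1.25) and Akr1b8 (-1.21). Cyp1a1 kept its call under every alternative that gave a value, while Aldh3a1 lost it in 8 of 15, with adjusted p values up to 0.38.

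**Figure D3:**
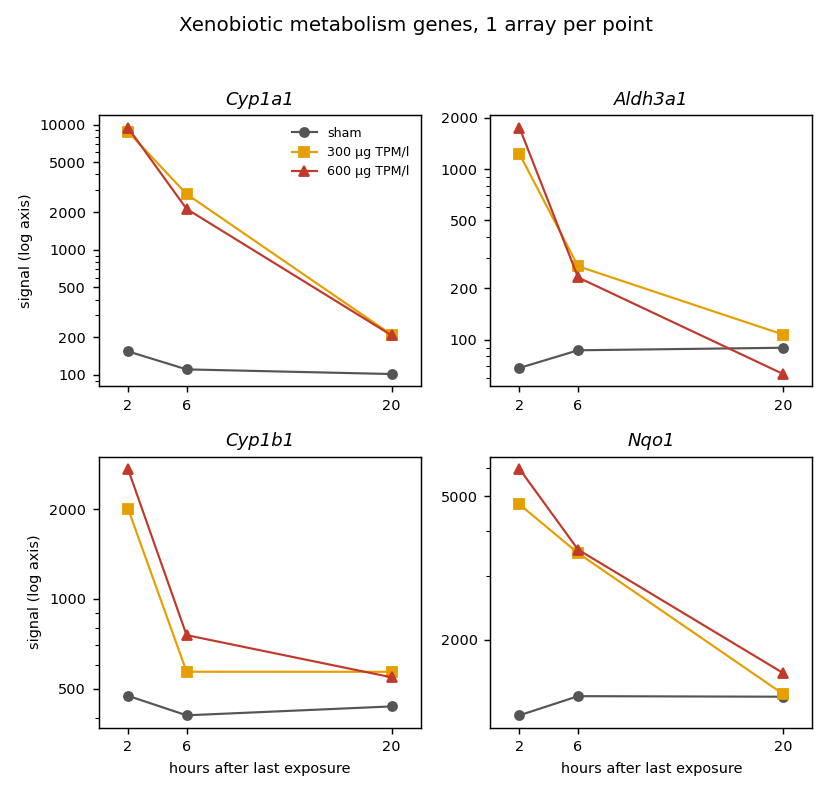
Signals (array units, log axis) of 4 xenobiotic metabolism genes against hours after the last exposure, 1 array per point. Both smoke groups start far above sham at 2 h and come close to it by 20 h, Cyp1a1 from 8795 and 9463 to 209 and 207.

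From 2 to 6 h, limma called 0 differences of the smoke effect, and 1231 probe sets had an unadjusted p under 0.05. The 5 genes with the smallest p, none past the threshold, were Per2 (-1.70), Aldh3a1 (-2.54), G0s2 (1.44), Anp32a (1.57) and Cyp1a1 (-1.54), with adjusted p values of 0.34 to 0.35. Adjusted over the list alone, 4 AhR genes had a lower smoke effect at 6 h than at 2 h. Of 17 core clock and clock output genes, 7 were lower when adjusted over the list alone, among them the clock output genes Dbp at -2.78 (SE 0.59) and Tef at -0.84 (SE 0.22), the repressor gene Per2 at -1.70 (SE 0.23) and Cry2 at -0.88 (SE 0.20). From 2 to 20 h, 4 clock genes had a higher effect when adjusted over the list alone, Per3 at 2.66 (SE 0.54), Nr1d1 at 2.25 (SE 0.66), Per1 at 1.57 (SE 0.36) and Tef at 0.74 (SE 0.22). No clock gene passed over all genes in either difference. Bmal1 (0.67 and -0.35) and Npas2 (0.82 and -0.38), partners that drive the loop, did not pass from 2 to 6 h or from 2 to 20 h under either adjustment. Per3, Tef and Npas2 were measured on type B, where the only sham array at 2 h is the doubtful one. Both differences of these genes rest on it, and no fit without it was possible.

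**Figure D4:**
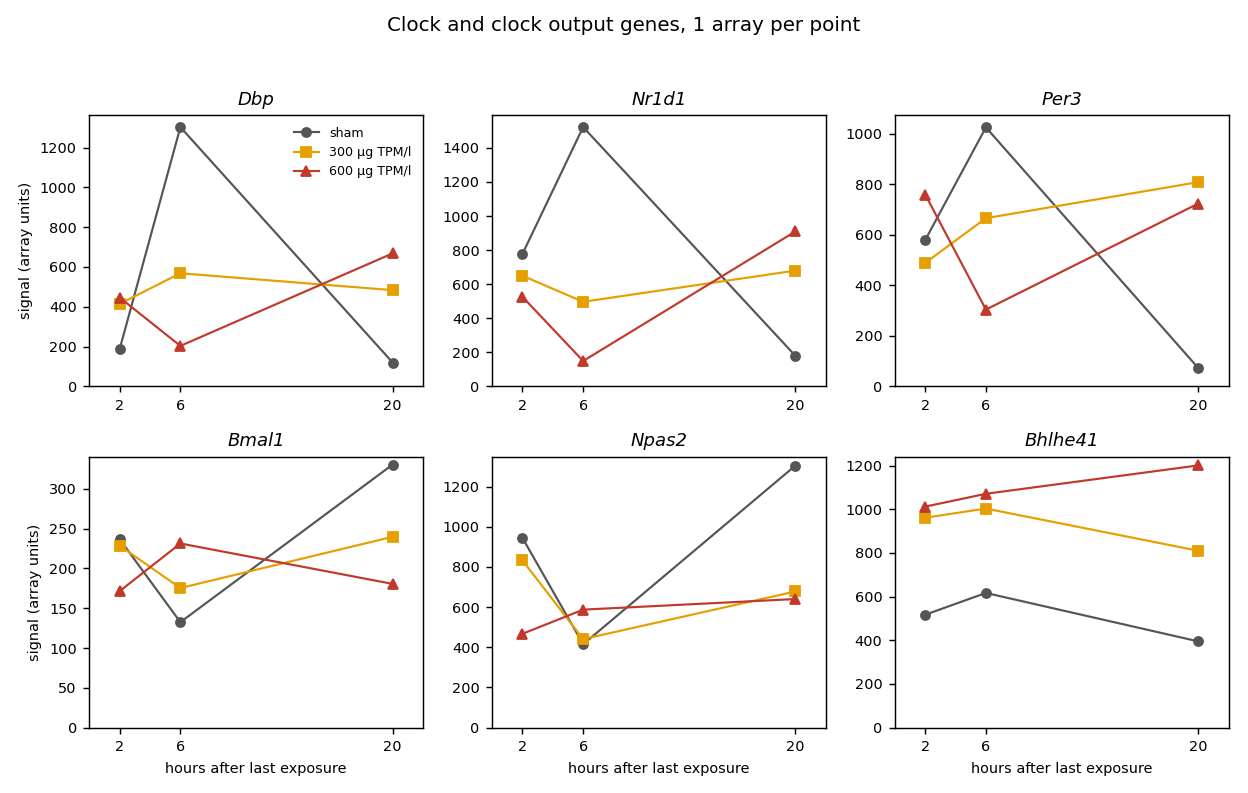
Clock genes in sham, 300 and 600 µg TPM/l against hours after the last exposure, 1 array per point. Dbp in sham goes from 189 at 2 h to 1303 at 6 h and 120 at 20 h, while at 600 µg/l it goes from 446 to 203 and 669. At 300 µg/l it goes from 415 to 568 and 484, highest at 6 h as in sham but flatter.

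Of 28 NRF2 genes, 26 were above sham at 2 h, 24 at 6 h and 20 at 20 h in the mean of both smoke levels, with medians of 0.42, 0.29 and 0.10. The macrophage list had medians of 0.47, 0.55 and 0.57 at the 3 times, and none of its 19 genes passed a difference between times. The chemokine list had medians of 0.35, 0.50 and 0.13. These values per time were computed after the main results were seen. For list members on type B the only sham array at 2 h is the doubtful one. The medians and counts at 2 h rest partly on it, so their course over the times is uncertain.

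**Figure D5:**
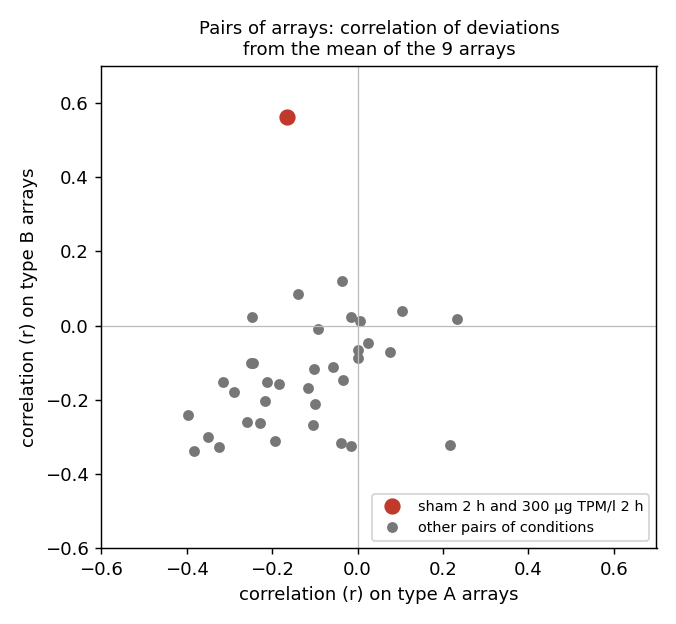
Correlation across probe sets of the deviations from the mean array, for each pair of conditions, on type A arrays (x axis) and type B arrays (y axis). The pair sham at 2 h and 300 µg/l at 2 h lies at -0.16 on type A and 0.56 on type B, above the other 35 pairs on type B.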

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

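The tests of the clock pattern below were chosen after the pattern was seen. That of exchanged sham labels replaced a first test that had not decided, and only its prediction was written before it was run.

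The smoke effect on Cyp1a1 and Aldh3a1 differed between 20 and 2 h by a test of the difference itself, by -4.72 (adjusted p = 2.3e-04) and -3.74 (adjusted p = 0.041) on the log2 scale. Aldh3a1 signals at 300 and 600 µg/l were 1225.1 and 1747 at 2 h, 269.5 and 231.8 at 6 h, and 107.3 and 63 at 20 h, against dim signals of 68.4 to 89.8 in sham.

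Other genes stood out because both smoke levels moved one way from sham at 1 time and the other way at another. From 6 to 20 h the mean difference from sham changed by 4.12 for Nr1d1 (from -2.25 to 1.87), by 3.64 for Dbp (from -1.77 to 1.87), by -1.74 for G0s2 (from 0.84 to -0.90), by -1.20 for Npas2 (from 0.27 to -0.93) and by -1.02 for Bmal1 (from 0.46 to -0.56). These differences from 6 to 20 h were not tested. From 2 to 6 h it changed by -1.70 for Per2 (from 1.51 to -0.19), by 1.57 for Anp32a (from -0.41 to 1.16) and by 0.83 for Ms4a7 (from -0.27 to 0.56). None of these 3 passed the limma comparison of the smoke effect at 6 and 2 h (adjusted p = 0.34, 0.34 and 0.78), and their opposite signs at both times were not tested. Each time has 1 sham array per type, so 1 sham array shapes all these differences at its time. For Ms4a7, on type B, that at 2 h is the doubtful array. The sham arrays at 6 h had the highest 3'/5' ratios of their type for GAPDH, 1.25 on A and 1.16 on B. Their hexokinase ratio was 4.52 on A, where the next was 3.27. On B it was 3.68, below the 4.72 of 300 µg/l at 20 h. Their actin ratios lay within the range of the others. Whether this shapes the differences at 6 h was not tested.

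Clock genes differed from sham in opposite directions at 6 and 20 h. Over the 17 clock genes the difference at 6 h correlated with that at 20 h at r = -0.72 (rho = -0.72, permutation p = 9.7e-04 and 0.0016, r = -0.65 without the 2 farthest genes), a correlation across genes, which are not independent replicates. This lay at percentile 0.17 of 10000 random lists of like expression, and the correlation over all tested genes was 0.12. Of the 17, 14 had opposite signs in both smoke levels, against 20.9% of other genes. Their median range over the 3 times was 0.91 in sham, 0.36 at 300 µg/l and 0.43 at 600 µg/l. These values describe the pattern that prompted them and do not test its cause. A displaced daily rhythm in smoke-exposed rats is a candidate explanation that stays open.

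Exchanged labels of the sham samples at 6 and 20 h could also give the same pattern. Outside the clock list the 20 h minus 6 h difference in sham correlated with that of smoke at -0.052 (interval -0.084 to -0.021). With 300 and 600 µg/l apart it was 0.040 and -0.061 on type A and -0.16 and 0.052 on type B, too mixed to decide. The differences at 300 and 600 µg/l did not go together either (r = -0.060). Without a time difference that the exposures share, this test cannot tell exchanged from correct sham labels. The first test, r = -0.49 over clock genes with the labels exchanged (interval -0.84 to 0.014), was open as well. Both intervals come from resampling genes and hold no variation between arrays. Exchanged labels and a displaced rhythm therefore cannot be told apart here, and the labels do not give the hour of day at which lungs were taken. Exchanged sham labels would leave the ranges in sham as they are, so alone they do not account for the smaller median ranges under smoke. A flatter course over the times under smoke was not tested.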

How the results depend on the processing

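Counts of calls moved under several settings. Type A alone and the settings without doubtful B arrays were chosen after the results were seen, and the rest before the data were examined. The cause was not tested, except that fewer arrays or other sets of tested probe sets change the spread and the adjustment. Counts of probe sets past the threshold follow.

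With no filter, which adds dim probe sets, there were 35 (of 101) for 600 µg/l against sham, 1 (of 9) for 300 µg/l against sham, 2 (of 4) for 600 against 300 µg/l, 19 (of 42) among exposures, 1 (of 3) for 6 against 2 h, 0 (of 10) for 20 against 2 h (limma, 3006 at an unadjusted p under 0.05) and 1 (of 2) for the smoke effect at 20 minus 2 h. With no intensity trend there were 54, 2 and 2 for the 3 pairs of exposures, 1 for each time comparison, and 1 for the effect at 20 minus 2 h. The 60th percentile filter gave 1 for 600 against 300 µg/l and 1 for the effect at 20 minus 2 h. Adjustment within each type gave 29 for 300 µg/l against sham, 72 among exposures, 28 for 20 against 2 h and 4 for the effect at 20 minus 2 h. Median scaling gave 22 for 20 against 2 h, quantile normalization 4 for the effect at 20 minus 2 h, and 0.25 times the pseudocount 1 there. With 4 times the pseudocount, 6 and 24 probe sets passed for 6 and 20 h against 2 h. Without the other factor, 22 passed for 20 against 2 h. With only the 2 exposures compared, 57 passed for 600 µg/l against sham and 2 for 600 against 300 µg/l. Without the 20 h conditions the counts were 55 and 18 against sham, 2 for 600 against 300 µg/l and 27 among exposures.

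Type A alone gave 29 for 300 µg/l against sham, 71 among exposures, 0 and 0 for 6 and 20 h against 2 h (limma, 856 and 818 at an unadjusted p under 0.05) and 4 for the effect at 20 minus 2 h. Leaving out the B array labelled sham at 2 h gave 1 and 0 for 6 and 20 h against 2 h (1587 unadjusted for the latter), and leaving out that labelled 300 µg/l at 2 h as well gave 0 and 0 (1201 and 1216 unadjusted).

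Leaving out 1 condition in turn, a lone array being assumed to vary like the others, gave 43 to 95 for 600 µg/l against sham (43, 58, 47, 48, 49 and 51 without 600 at 20 h, sham at 20 h, 600 at 2 h, sham at 2 h, sham at 6 h and 600 at 6 h). For 300 µg/l against sham it gave 2 to 14 (2 without sham or 300 at 2 h, 3 without 300 at 6 h, 4 without sham at 6 h, 14 without 600 at 6 h or sham at 20 h). For 600 against 300 µg/l it gave 1 to 4 (1 without 300 at 2 h or 600 at 6 h, 2 without 600 at 2 h, 300 at 20 h or 600 at 20 h), and among exposures 29 to 51. For 6 against 2 h it gave 1 to 7 (7 without 600 at 2 h, 6 without 300 at 6 h, 1 without 300 at 2 h, sham or 600 at 6 h, or 300 or 600 at 20 h). For 20 against 2 h it gave 0 to 18 (0 without 300 at 2 h or 20 h, with 1275 and 1610 at an unadjusted p under 0.05, 1 without 600 at 20 h, 4 without sham at 20 h, 6 without 600 at 2 h, 17 without sham at 6 h, 18 without 300 at 6 h). The effect at 20 minus 2 h had 1 to 2 calls (1 without any smoke condition but 300 at 20 h), and that at 6 minus 2 h 0 to 1 (1 without 300 at 2 h). Of 47 list calls, camera with an estimated correlation kept 0 and fry 3. Those 3 were at 600 µg/l against sham, the macrophage, acute inflammatory and T cell lists (fry adjusted p = 0.030, 0.030 and 0.048).

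Some genes not past the threshold in either fit changed sign. For 600 µg/l against sham, leaving out 1 condition gave -0.51 to 1.31 for Dbp (negative also without sham at 2 h, -0.08, 600 at 2 h, -0.05, and 600 at 20 h, -0.39), -1.54 to 0.52 for Nr1d1 (0.40 without 600 at 6 h) and -0.46 to 0.073 for Bmal1 (0.04 without 600 at 20 h). Without the 20 h conditions Dbp was -0.68 and Bmal1 0.13. For 300 µg/l against sham, leaving out 1 condition gave -1.10 to 0.97 for Nr1d1 (0.03, 0.06 and 0.09 without sham at 2 h, 300 at 2 h and 300 at 6 h), -0.062 to 0.30 for Gclc, -0.33 to 0.19 for Bmal1 (0.0098 without sham at 2 h) and -0.26 to 1.57 for Dbp. Without the 20 h conditions Bmal1 was 0.13 and Dbp -0.084. With 0.25 times the pseudocount Nr1d1 was 0.0012. For the effect at 20 minus 2 h, Npas2 ran from -0.76 to 0.0080 (without 300 at 2 h). For the other values of genes and lists in the text, 3465 alternatives kept direction and side of the threshold, 329 lost a call and 76 gained one. For list members that the rule names and the text does not, 179 values changed sign, 11392 kept direction and side, and 19 gained a call. Sftpc at 20 h was left out of the text after its sign under quantile normalization was seen.

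No value came from a linear slope except for 600 µg/l against sham, from only the 2 exposures for the F test and time comparisons, from leaving out the 20 h conditions for the time comparisons, or for the differences of smoke effects from these, from leaving out a compared sham array or the doubtful B arrays, or without the other factor. No paired analysis was possible because the labels give no replicate numbers, with 1 array per condition and type. Exposures were compared within recovery times by the first model, and without the time term 106 probe sets passed for 600 µg/l against sham, 82 of them shared with the 101.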

Other observations

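The tests of the B array, of the macrophage genes and of other splits were chosen after the results were seen.

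In the values per recovery time, the immediate early genes Egr1 and Ier3 stood above sham at 2 h, Egr1 at 1040.6 and 1133.3 against 581 and Ier3 at 1195.9 and 1157.9 against 683.6. At 20 h Egr1 read 549.2 and 609.8 against 996. The smoke effect from 2 to 20 h was lower by 1.58 for Egr1 (adjusted p = 0.66), by 0.93 for Fos and by 0.65 for Ier3, past only when adjusted over the list alone, where 3 of 17 genes passed. Interferon-responsive genes had medians of -0.30, -0.11 and -0.10 at 2, 6 and 20 h, NK and cytotoxic genes of -0.42, -0.19 and -0.10, and sterol and fatty acid genes of -0.08, 0.36 and 0.20. The medians at 2 h rest partly on the doubtful B array, through the members on type B. Smoke against sham at single times passed for 14, 2 and 0 probe sets at 2, 6 and 20 h in limma (1010, 1938 and 1144 at an unadjusted p under 0.05), which does not show a difference between times.

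Genes chosen after their values were seen include Sod2, the mitochondrial superoxide dismutase gene, which rose by 0.97 at 600 µg/l (SE 0.09, adjusted p = 0.0012) and stood at 0.56 at 300 µg/l (adjusted p = 0.077). The neutrophil chemokine receptor gene Cxcr1 rose by 0.82 at 600 µg/l (SE 0.11, adjusted p = 0.012) and stood at 0.72 at 300 µg/l (adjusted p = 0.077). On type B, Ahrr read 839 and 533 at 300 and 600 µg/l at 2 h, 885 on the doubtful array labelled sham at 2 h, and 163 to 264 in the later arrays.

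The B array labelled sham at 2 h resembled that labelled 300 µg/l at 2 h. A batch of all 3 B arrays at 2 h would hold the arrays labelled sham and 600 µg/l together, and their correlation was 0.023. Little difference between the lungs would show on type A too, where the correlation was -0.16 and Cyp1a1 read 8795 at 300 µg/l against 154 in sham. Over the 100 probe sets on both types the B array correlated better with the A array labelled 300 µg/l at 2 h than with that of its own label, by 0.32 (interval 0.12 to 0.51). The B array labelled 600 µg/l at 2 h also correlated best with that A array (0.21, against -0.033 with its own). This measure therefore does not single out the array labelled sham, and whether other RNA is on it stays open. Only 3 of 9 B arrays correlated best with their own A array over these probe sets. Over 1417 genes on both types, where 7 of 9 did, the difference was 0.076 (interval -0.0018 to 0.15). There the array labelled sham correlated best with the A array labelled 600 µg/l at 2 h (0.099). The intervals come from resampling probe sets or genes and hold no variation between arrays.

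Of 19 macrophage genes 8 rose at 600 µg/l (list adjusted p = 0.32 with an estimated correlation), and none of the T, B and NK cell genes did. A lower share of the main lung cell types would raise every other cell type alike. The median of 19 macrophage genes (0.63) exceeded that of 28 T, B and NK cell genes (-0.20) by 0.83 (permutation p = 1e-05, the smallest possible). The permutation exchanged genes, which are not independent replicates, so its p-value does not measure the spread between arrays. The medians argue against that explanation taken alone, and do not exclude it beside a separate change of the lymphoid genes. More macrophages, or more of these transcripts per macrophage, may each lie behind these 8 calls, and nothing here separates them.

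Each comparison of 3 with 3 conditions has 10 splits, too few for a share under 0.05. The real split gave 101 probe sets for 600 µg/l against sham (highest other 2), 9 for 300 µg/l against sham (1), 4 for 600 against 300 µg/l (0), 3 for 6 against 2 h (0) and 10 for 20 against 2 h (0), so 1 split, the real one, reached each value. For the test among exposures, 100 of the 252 partitions that can be fitted (of 280) were drawn, after a first draw had held some that cannot be fitted. The real one gave 42, 1 of 100. The highest other gave 39 and kept the 3 sham conditions together, but most of the drawn partitions are unbalanced over the recovery times, unlike the real one. Of the 36 partitions with 1 condition of each time per group, 1, the real one, gave as many (highest other 7). That is the smallest share these partitions allow. It lies under 0.05 for this count, without allowance for the draw before it, and does not bear on single pairs of exposures.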
